A study of Sus scrofa with 24 samples.

How the data were processed

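The series holds RNA sequencing of the longissimus dorsi, the long muscle of the back, from 24 pigs. Per the labels, the animals came from 265 F1 pigs bred from 8 Duroc boars and 112 Luchuan sows, fed alike on 1 farm and slaughtered at 210 ± 6 days. Muscle was taken 25 minutes after death, and polyA RNA was sequenced as 150-base read pairs. The labels class 12 animals as high and 12 as low in intramuscular fat (IMF). The fat content of each animal, its litter and its batch are not used here. No label of sex is used either, and the level of Y-linked genes stands in for it.

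The authors deposited 1 table of FPKM values, 1 value per assembled transcript and animal. That the unit is FPKM was inferred from the values, which are not whole and do not sum to a constant, and from the columns beside them. The submitters' processing notes name HISAT2 2.0.5, StringTie 1.3.3 and the pig genome Sscrofa11.1, without their roles; the annotation release is not given in the sources used here. Coordinates are those of the deposited table. The authors' deposited table also gives a fold change, a p-value and 3 kinds of q-value per transcript, per the file headers. The fold change is low over high IMF: its sign matched the FPKM means for all 328 transcripts with an authors' p-value under 0.01. How the authors computed it, and what separates the 3 q-values, is not given in the sources used here.

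The table lists 22154 transcripts: 12404 reference transcripts, 7985 isoforms added by the assembly and 1765 transcripts at other loci. Each is above 0 in at least 19 of the 24 libraries, and 16435 are above 0 in every library, so genes seen in fewer animals are not analysed here. FPKM was summed over the listed transcripts of a gene symbol on a chromosome, or of a locus without a symbol, giving 12017 genes, of which 9506 have a symbol. The 52 symbols on more than 1 chromosome or scaffold were kept apart, and DGAT2 below is the locus on chromosome 9. In 34 transcripts a date stands in place of the symbol, and these were kept by locus. Reads shared between transcripts or between near-identical genes were divided by the authors' assembly, so values of isoforms and paralogs are less certain than sums.

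The table states no depth, so depth is known only by inference. FPKM multiplied by transcript length moves in steps of 1 base of coverage, and the step gives what 1 read of 150 bases is worth. The step was taken, per library, as the value that brought most of the 134 to 253 low values at single-transcript loci within 0.05 base of a whole number. This held for 72.9% to 84.1% of them, against 29.8% to 53.4% for the next best step of the same search. The estimate was 32.9 to 40.8 M reads per library (M for mega), and 1 read on a transcript of 1 kilobase was worth 0.0245 to 0.0304 FPKM. Whether the authors' denominator counted reads or pairs is not known, so these depths are relative. The values are base coverage and not whole reads, so no count model was used.

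The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend and robust moderation, high minus low IMF, on the 11757 genes with a mean of at least 0.5 FPKM. Benjamini-Hochberg adjustment used a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Each library is 1 animal. Values are mean ± SD of FPKM over 12 animals per group.

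Before the data were examined, 22 gene lists with 397 symbols were fixed; 320 symbols are in the table and 77 were not matched. TRARG1 of the adipocyte list is among the unmatched, although TUSC5, under which the table lists a gene, is an earlier symbol of it. The 20 lists with at least 5 tested members were tested with camera, which asks whether a list stands apart from other genes, at a preset inter-gene correlation of 0.01, two-sided. The alternatives were a correlation estimated per list and fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. A list level per animal, the mean z score of log2(FPKM + 1) over its members, was compared by a two-sided permutation test with 100000 resamples in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, adjusted over the 22 lists. Named genes followed a rule set at the same time. It is limited to genes with a symbol. It takes all called genes with a mean of at least 1 FPKM, filled up by smallest p among such genes to 10 per direction. It adds the 5 of smallest p per direction, and up to 4 members per list by smallest p. Other genes in the text were chosen after their values were seen.

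Alternatives set at the same time were scaling by trimmed mean of M values (TMM) or upper quartile, no filter, a mean of at least 5 FPKM, limma without robust moderation or with array weights, a pseudocount of 0.1, the first 4 digits of the animal identifier as a term, 1 animal per shared 9 identifier digits, and the Y-linked level as a term. Added after seeing the data were transcripts as units, reference transcripts alone, each animal left out, a pair of libraries left out together, and TMM scaling of list levels. Transcript use within genes was tested with limma's diffSplice. The procedure was tested on 11757 simulated genes with independent noise. It recovered 54.7% of 53 changes of 0.5 log2, 90.9% of 77 changes of 1 and 98.6% of 70 changes of 1.5, with 5 false among 173 calls. Only genes with a mean log2 value above 1 were changed, so this does not cover low genes such as LEP. More genes were changed than were called in the real data, which eases the adjusted threshold. Of 200 simulated null lists, 1 had a camera p under 0.05. On the real values camera was less strict: in 92 of 99 other splits of the 24 animals at least 1 of the 20 lists passed the adjusted threshold.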

Results

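The muscle transcriptome was compared between 12 pigs of high and 12 pigs of low IMF, drawn from the extremes of a Duroc × Luchuan cross. The question was which transcripts differ in muscle between animals that store much and little fat within it. Summed FPKM per library was 351119 to 415572, and the estimated depth was 36.2 ± 2.43 M reads in high and 36.9 ± 1.28 M reads in low IMF (SD, n = 12 each, permutation p = 0.400). The 10 most abundant genes took 26.8 ± 2.55% of FPKM in high and 29.3 ± 3.79% in low IMF (permutation p = 0.0713). That share was 18.5% in low IMF animal 10 and 20.2% in high IMF animal 7, and at least 24.7% in the other 22. Animals are numbered within a group in accession order. EIF1AY, a Y-linked gene, was below 1 FPKM in 5 of 12 high and 3 of 12 low IMF animals (Fisher's exact p = 0.667).

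LEP, which encodes the fat cell hormone leptin, was 5.08-fold higher in high IMF muscle, at 0.888 ± 0.469 against 0.175 ± 0.0828 FPKM. TUSC5, a fat cell protein of insulin-regulated glucose transport, was 7.27 ± 3.36 against 2.46 ± 1.83 FPKM. SDR16C5, a retinol dehydrogenase, was 1.91 ± 0.913 against 0.493 ± 0.287 FPKM. AGT, which encodes angiotensinogen, was 12.5 ± 2.76 against 6.20 ± 2.83 FPKM, and ATP6V1F, a subunit of the vacuolar proton pump, was 52.5 ± 8.70 against 34.3 ± 4.52 FPKM.

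Of 11757 genes tested with limma, these 5 were higher past the adjusted threshold and 1 was lower, which is not analysed here. The log2 fold change was 0.65 (SE 0.102, adjusted p = 0.00697) for LEP and 0.60 (SE 0.0944, adjusted p = 0.00697) for ATP6V1F. It was 0.91 (SE 0.153, adjusted p = 0.0108) for SDR16C5, 1.29 (SE 0.224, adjusted p = 0.0138) for TUSC5 and 0.98 (SE 0.178, adjusted p = 0.0206) for AGT. All 12 high IMF animals lay above the low IMF median in LEP, ATP6V1F, TUSC5 and AGT, and 11 did in SDR16C5. LEP lies on chromosome 18 at 20106179 to 20123451, with 3 exons in the listed transcript, and ATP6V1F on the same chromosome at 19753759 to 19756658, with 2 exons. SDR16C5 lies on chromosome 4 at 75586235 to 75599786, TUSC5 on chromosome 12 at 46621117 to 46634332 and AGT on chromosome 14 at 59643254 to 59657798.

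**Figure D1:**
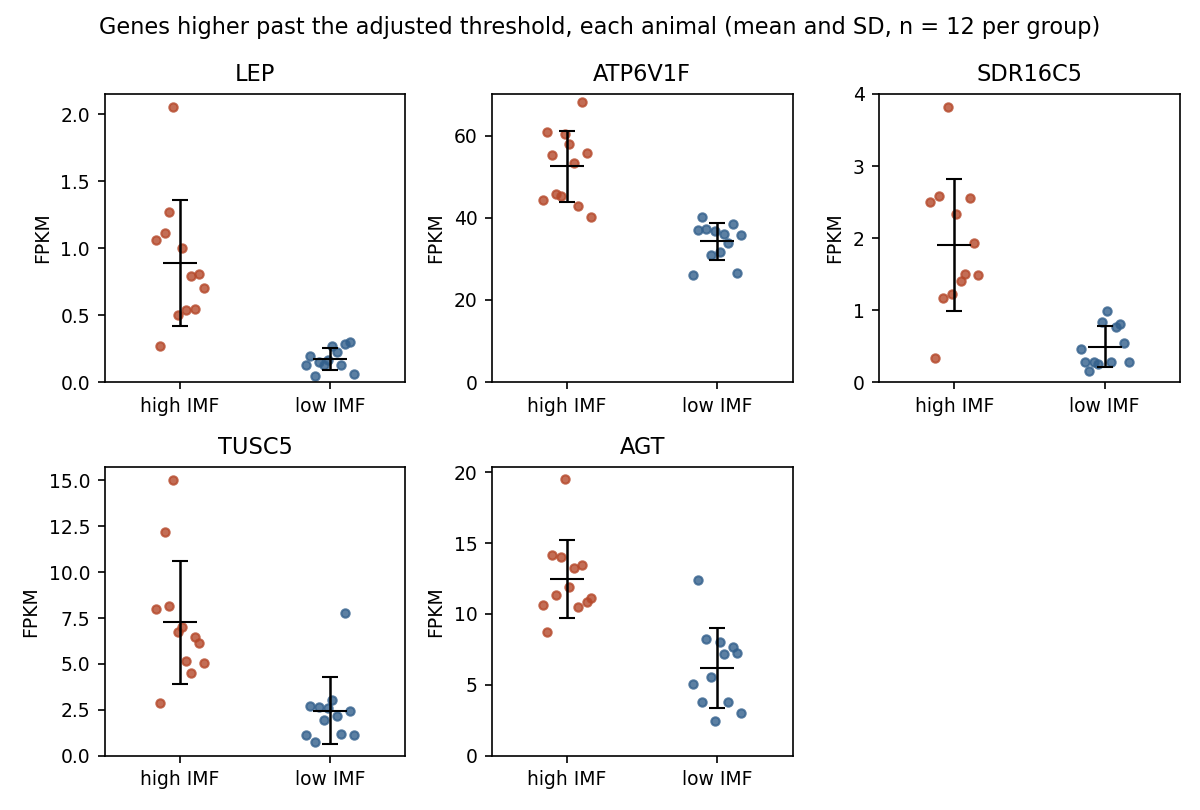
FPKM of the 5 genes higher past the adjusted threshold, 1 point per animal for 12 high and 12 low IMF animals, with the group mean (bar) and SD (whiskers); each vertical axis starts at 0. LEP averages 0.888 FPKM in high and 0.175 in low IMF, and TUSC5 7.27 in high and 2.46 in low IMF.

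At an unadjusted p under 0.05, 798 genes were higher and 105 lower in high IMF, where chance gives 588 in all. With TMM scaling these were 330 and 275, or 54.5% higher in place of 88.4%, and the median log2 fold change of all genes moved from 0.077 to -0.000855. With upper-quartile scaling they were 294 and 297. In all, these 2 scalings gave close to the number that chance gives, 586 and 587. TMM scaling called 4 genes higher (LEP, TUSC5, SDR16C5 and ADIPOQ) and 2 lower, among them PRX. It ended the calls of ATP6V1F (log2 fold change 0.48, adjusted p = 0.0665) and AGT (0.88, adjusted p = 0.0569). Without low IMF animal 10, 29 genes were higher and 2 lower, and without high IMF animal 5 the counts were 3 and 0. They were 8 and 2 without high IMF animal 2, and 8 and 0 without high IMF animal 9. Without low IMF animal 10 and high IMF animal 7 they were 18 and 3, and LEP, ATP6V1F, SDR16C5, TUSC5 and AGT stayed past the threshold.

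Among the next genes by p, ADIPOQ, which encodes adiponectin, was 27.1 ± 12 against 10.3 ± 5.72 FPKM (limma log2 fold change 1.32, adjusted p = 0.0544). DGAT2, an enzyme of the last step of triglyceride synthesis, was 16.2 ± 7.58 against 5.38 ± 3.13 FPKM (1.44, adjusted p = 0.0693). PPP1R1B (0.79, adjusted p = 0.0693), the secreted superoxide dismutase SOD3 (0.63, adjusted p = 0.0857) and lipoprotein lipase LPL (0.75, adjusted p = 0.105) did not pass either. In the other direction, PRX, which encodes periaxin, was 1.06 ± 0.583 against 2.29 ± 0.846 FPKM (-0.68, adjusted p = 0.0693). The keratin KRT14 was 0.519 ± 0.424 against 1.44 ± 0.832 FPKM (-0.68, adjusted p = 0.118), with all 12 low IMF animals above the high IMF median. The next genes that the naming rule took in that direction were AATK, KRT8, DDX20, TAPAN4, BEX1, GOLGA2, MYOM1, CRADD, ZNHIT6 and MYH14, with limma adjusted p from 0.216 to 0.391. The rule leaves out loci without a symbol and, past the first 5, genes with a mean under 1 FPKM.

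In the authors' deposited table, 851 transcripts were higher in high IMF and 564 higher in low IMF at a p-value under 0.05. Of the 3 kinds of q-value in the authors' deposited table, the first was under 0.05 for 1 transcript, the second for 3 and the third for 5. The transcript of SNCG (fold low over high 0.773) passed all of them, at 0.01, 0.004 and 0.002. LEP (0.653) and ATP6V1F (0.665) each had 0.113, 0.045 and 0.023. The authors' fold for LEP was much nearer to 1 than the 5.08-fold ratio of FPKM means given above, so the 2 are not on the same scale. SDR16C5 (0.56), higher in high IMF, and ARID3A (1.181), higher in low IMF and named after its values were seen, each had 0.214, 0.094 and 0.049. TUSC5 (0.462), higher in high IMF, had 0.214, 0.097 and 0.051 and so passed none. No transcript of AGT passed any of them. SNCG, named after its values were seen, encodes gamma-synuclein and lay below the 0.5 FPKM filter, and it passed the limma test when no filter was applied.

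Genes of fat cells were higher together in high IMF muscle. Of 13 measured adipocyte markers, 11 had a positive log2 fold change, with a median of 0.64. Of these 13, LEP passed over all genes tested, and 8 rose when adjusted over the list alone: LEP, ADIPOQ, CIDEA, ADIG, FABP4, THRSP, CIDEC and PPARG. TUSC5, which also passed over all genes, is listed as TRARG1, its later symbol, and so was not counted among the 13. FABP4, the fat cell fatty acid binding protein, was 64.4 ± 24.7 against 37.6 ± 19.5 FPKM, and CIDEC, a lipid droplet protein, was 5.72 ± 2.40 against 2.78 ± 2.16 FPKM. The remaining markers stayed closer to 0 in log2 fold change: PLIN4 0.19, CFD 0.17, GPD1 0.056 (-0.057 with TMM scaling), GPAT3 -0.013 and the droplet coat protein PLIN1 -0.088 (SE 0.510). With TMM scaling 10 of the 13 were positive and 8 passed when adjusted over the list alone. GPD1 and PLIN4 are also made by muscle fibres and FABP4 by vessels. The list differed by camera (adjusted p = 5.88e-09), with an adjusted p = 0.0132 with an estimated correlation and 0.000247 by fry.

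The adipocyte level per animal was 0.415 ± 0.410 in high and -0.415 ± 0.331 in low IMF (adjusted permutation p = 0.00132), and all 12 high IMF animals lay above the low IMF median. By the first 4 digits of their identifiers the animals fall into 2 sets, each with 6 high and 6 low IMF animals, and what the digits mean is not given in the sources used here. High exceeded low IMF by 0.678 within the set of the smaller number (exact permutation p = 0.00217, the smallest it can give, n = 6 each). Within the other set the difference was 0.981 (exact permutation p = 0.00433, n = 6 each). With a mean of at least 5 FPKM, which drops several markers, the camera call was lost (adjusted p = 0.089).

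Genes that make and store fatty acids followed. Of 21 measured genes of fatty acid and triglyceride synthesis, 17 were positive and none passed over all genes, while 8 rose when adjusted over the list alone: DGAT2, ELOVL6, ELOVL5, FASN, SCD, ME1, MLXIPL and TKT. With TMM scaling 3 passed when adjusted over the list alone, and the list median moved from 0.25 to 0.15. Fatty acid synthase FASN was 16.2 ± 9.60 against 8.05 ± 5.46 FPKM, and the elongase ELOVL6 was 1.68 ± 0.780 against 0.677 ± 0.703 FPKM. ACLY, at -0.34, PGD, at -0.074, and the desaturases FADS1 and FADS2, at -0.0075 and -0.034, had no positive log2 fold change. The camera test gave adjusted p = 6.02e-05, with an adjusted p = 0.149 with an estimated correlation. The level per animal differed (adjusted permutation p = 0.0243), and 11 of 12 high IMF animals lay above the low IMF median.

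**Figure D2:**
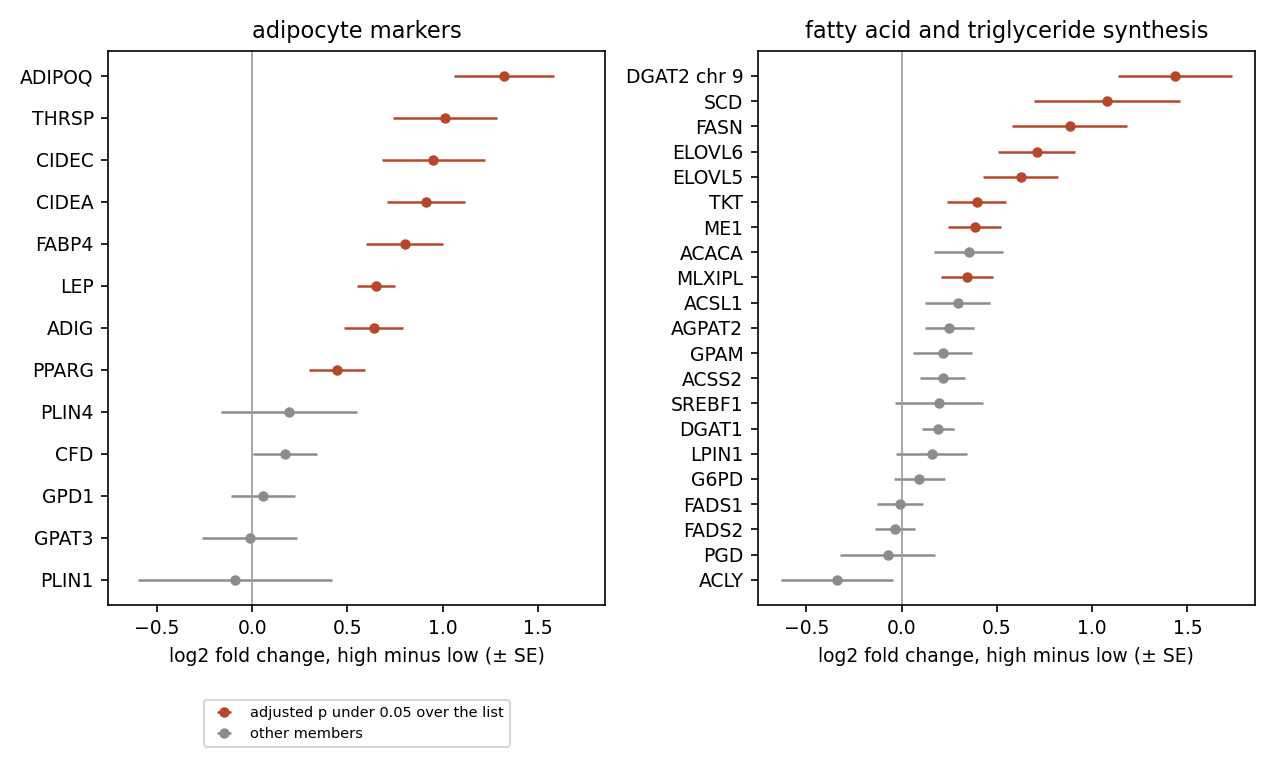
Log2 fold change (high minus low IMF, log2(FPKM + 1) scale) with its SE for each measured adipocyte marker and each measured gene of fatty acid and triglyceride synthesis, 12 animals per group; coloured points passed when adjusted over the list alone. ADIPOQ at 1.32 and DGAT2 at 1.44 lie highest, and PLIN1 at -0.088 and ACLY at -0.34 lowest.

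Of 12 genes of lipolysis, 4 rose when adjusted over the list alone: PRKAR2B, NPR1, the hormone-sensitive lipase gene LIPE and ABHD5. LIPE was 13.9 ± 5.69 against 8.03 ± 6.59 FPKM. The list passed by camera (adjusted p = 0.0191) but had an adjusted p = 0.356 with an estimated correlation and 0.0571 by fry. Without high IMF animal 8 it had a camera adjusted p = 0.0518, and without low IMF animal 12 one of 0.0751. Of 13 genes of fatty acid uptake and transport, LPL, APOE and FABP3 rose when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0968) but passed fry (adjusted p = 0.0459), and camera without high IMF animal 3 (adjusted p = 0.0492). LPL was 30.1 ± 10.3 against 17.4 ± 4.83 FPKM.

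Genes of oxidative phosphorylation and the TCA cycle were higher by small amounts, positive in 22 of 23 measured genes with a median of 0.18 (18 of 23 and 0.065 with TMM scaling). No member passed, over all genes or adjusted over the list alone, though 6 had an unadjusted p under 0.05 in the limma fit. COX5B was 119 ± 19.6 against 100.5 ± 13.6 FPKM and NDUFB8 was 79.9 ± 11.9 against 68.6 ± 8.21 FPKM. The list passed camera (adjusted p = 6.02e-05), with an adjusted p = 0.270 with an estimated correlation. Its level per animal differed (adjusted permutation p = 0.0411), and this call was lost with TMM scaling (adjusted permutation p = 0.508), while the list passed camera with TMM scaling (adjusted p = 0.0156). Genes of fatty acid beta-oxidation, positive in 20 of 23, lay close to the camera threshold (adjusted p = 0.0509). They passed with TMM scaling (0.0486) and for 12 of the 24 animals left out (0.00497 to 0.194). They did not pass with upper-quartile scaling (0.0518) or with an estimated correlation (0.553).

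Fast-twitch fibre genes were lower than other genes by camera (adjusted p = 0.00194), with an adjusted p = 0.149 with an estimated correlation and 0.558 by fry. Of 14 measured, 9 were negative with a median of -0.13, and none passed over all genes or adjusted over the list alone. MYLPF, a fast myosin light chain, was 3682 ± 1546 against 4859 ± 1100.1 FPKM. The calcium store protein CASQ1 was 470 ± 183 against 323 ± 234 FPKM, with a log2 fold change of 1.32 (SE 0.651). For CASQ1, 7 of 12 high IMF animals lay above the low IMF median, and low IMF animals 7 and 12 had 2.65 and 20.8 FPKM. The level per animal did not differ (adjusted permutation p = 0.549). Slow-twitch genes (adjusted p = 0.0516) and glycolysis genes (adjusted p = 0.0516) did not pass camera, and both calls turn on single animals. Slow-twitch genes passed for 9 of the 24 animals left out (0.000427 to 0.345) and glycolysis genes for 10 (0.00149 to 0.302).

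Schwann cell and nerve markers, as a list, were lower than other genes by camera (adjusted p = 0.000719), with an adjusted p = 0.0419 with an estimated correlation and 0.117 by fry. Of 10 listed genes 5 were measured, the fewest taken for camera. Only 1 of these had an unadjusted limma p under 0.05, so the call rests on few genes. The list level per animal did not differ (adjusted permutation p = 0.199), and the members of this list are not described here.

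**Figure D3:**
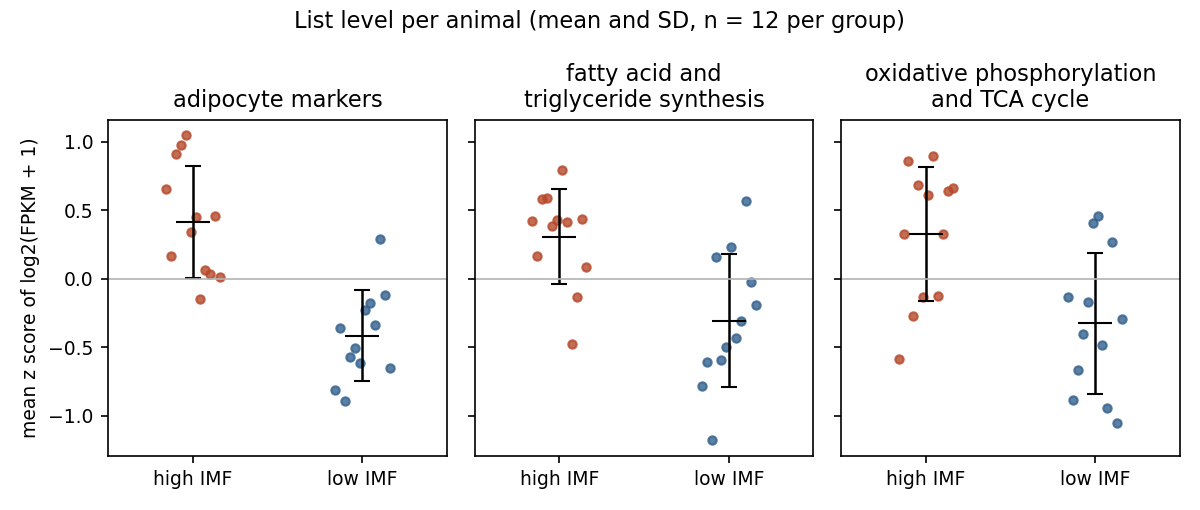
List level per animal, the mean z score of log2(FPKM + 1) over the members of a list, for 3 lists, 1 point per animal, with the group mean (bar) and SD (whiskers) for 12 high and 12 low IMF animals. The adipocyte level averages 0.415 in high and -0.415 in low IMF, and the synthesis level 0.306 in high and -0.306 in low IMF.

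Endothelial, smooth muscle, macrophage and fibroblast markers did not pass camera. The adjusted p was 0.30 for endothelial, 0.246 for smooth muscle and pericyte, 0.463 for macrophage and 0.372 for fibroblast and matrix genes. COL5A2, at 2.58 ± 3.58 against 5.47 ± 3.30 FPKM, and CDH5, at 10.6 ± 2.51 against 7.32 ± 2.73 FPKM, had the smallest p of the matrix and endothelial lists, and neither passed when adjusted over the list alone. Satellite cell genes (adjusted p = 0.0968), interferon genes (0.0561, but 0.000581 to 0.464 with 1 animal left out, passing for 10 of 24), immediate early and heat shock genes (0.122) and genes of adipogenesis, atrophy and cholesterol synthesis (0.754 each) did not pass. Of the adipogenesis regulators, the transcription factor CEBPA rose when adjusted over the list alone, at 9.40 ± 2.70 against 5.17 ± 2.78 FPKM. Lymphocyte markers (1 measured) and blood cell RNA (3 measured) were too few for camera, and their levels did not differ (adjusted permutation p = 0.292 and 0.207). HBB, the beta-globin gene, was 74.9 ± 55.6 against 40.1 ± 23.2 FPKM.

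Median, mean and camera direction differ in sign for 8 lists, none of which passed. Camera placed them below other genes, while the median or the mean was positive: glycolysis, slow-twitch, matrix, smooth muscle, satellite cell, adipogenesis, atrophy, and immediate early and heat shock genes.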

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

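The alternatives with transcripts as units, with reference transcripts alone, with animals left out and with TMM-scaled list levels were chosen after the data were seen. Over 103 named genes, 3631 of 3636 values under an alternative kept their sign. These genes were taken by smallest p in the same animals that the alternatives refit, so kept signs are no independent support. LEP, SDR16C5 and TUSC5 passed in every alternative in which they were above the filter; LEP falls below it without high IMF animal 4 or 5. AGT lost its limma call with TMM (adjusted p = 0.0569) and upper-quartile scaling (0.0628), with reference transcripts alone (0.63) and without high IMF animal 5 (0.0625). ATP6V1F lost its limma call with TMM (adjusted p = 0.0665) and upper-quartile scaling (0.0628). The cause of these and the following changes was not tested. Genes lower in high IMF were 2 with TMM and 2 with upper-quartile scaling, 3 with array weights, 3 without the pair of libraries of low top-10 share, and 0 with a pseudocount of 0.1, identifier digits, 1 animal per 9 digits, the Y-linked level or transcripts as units. At an unadjusted p under 0.05 those fits had 100, 108, 98, 98 and 234 lower. Genes higher were 3 with at least 5 FPKM, where fewer genes are tested, 23 with array weights and 18 without that pair. Leaving out 1 animal gave 3 to 29 higher (8 without high IMF animal 2 or 9) and 0 to 2 lower. Camera passed 10 lists with 1 animal per 9 digits, 10 without that pair, 2 with an estimated correlation and 6 to 10 with 1 animal left out (10 without high IMF animal 2 or 6). Calls were lost with at least 5 FPKM for adipocyte (0.089) and lipolysis (0.197) genes. With an estimated correlation they were lost for synthesis (0.149), lipolysis (0.356), oxidative phosphorylation (0.27) and fast-twitch genes (0.149), and with fry for lipolysis (0.0571), fast-twitch (0.558) and nerve genes (0.117). Leaving out 1 animal gave lipolysis 0.00466 to 0.0751, past 0.05 without high IMF animal 8 (0.0518) or low IMF animal 12 (0.0751). The level of oxidative phosphorylation genes lost its call with TMM scaling (0.508). Lists that had not passed gained a call in some alternatives: interferon genes in 5 of 14 (lowest adjusted p 0.00169), beta-oxidation genes in 4 (0.0148), glycolysis genes in 4 (0.00213), slow-twitch (0.00207) and uptake genes (0.0425) in 2 each, and smooth muscle (0.0453), macrophage (0.0311) and satellite cell genes (0.00847) in 1 each. With 1 animal left out, immediate early genes passed for 4 of 24 (0.00972 to 0.749) and satellite cell genes for 2 (0.0221 to 0.302).

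Signs turned for results that had not passed. With TMM and upper-quartile scaling adipogenesis genes turned (0.925 and 0.881). Fry turned matrix (0.835), smooth muscle (0.988), satellite cell (0.988), adipogenesis (0.558), atrophy (0.558) and immediate early genes (0.988). Reference transcripts alone turned the gene PRKAG3 (-0.11), the gene COL14A1 (-0.066) and the gene NCAM1 (0.20). Leaving out 1 animal turned IFI44 (-0.025 to 0.26) and, in camera adjusted p, cholesterol (0.283 to 0.996), atrophy (0.374 to 0.957), macrophage (0.116 to 0.904) and matrix genes (0.0861 to 0.805). List levels turned without z scores for smooth muscle (0.886) and satellite cell genes (0.933), with 1 animal per 9 digits for slow-twitch (0.938) and satellite cell genes (0.773), and with TMM scaling for glycolysis (0.688), matrix (0.949), smooth muscle (0.688), satellite cell (0.684), atrophy (0.949) and immediate early genes (0.91). No paired analysis was possible because the labels give no replicate numbers, and numbers in accession order pair no animals. Alternatives planned for counts were not run, since the values are FPKM.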

Other observations

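The tests on TMM scaling, on sequencing depth, on the adipocyte list over other splits and on the markers without GPD1, PLIN4, CFD and FABP4 were chosen after the results were seen. Among 8 relations computed, LEP and ADIPOQ had a Pearson's r of 0.58 in high (permutation p = 0.0485, adjusted 0.0969; Spearman's rho 0.68, p = 0.0186, adjusted 0.0746) and r 0.76 in low IMF (permutation p = 0.00373, adjusted 0.00995; rho 0.60, p = 0.0425, adjusted 0.0849). Without the 2 farthest animals r was 0.38 and 0.61. ATP6V1F and ADIPOQ had r -0.027 in high and -0.13 in low IMF (permutation p = 0.933 and 0.691, adjusted 0.933 and 0.789; rho -0.070 and -0.11, p = 0.834 and 0.733), with r -0.53 and -0.20 without the 2 farthest. Of 42 relations of the adipocyte level with other lists within a group, none passed adjustment.

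Fat cell genes rose in high IMF muscle, which may reflect more fat cells in the sample or more of these transcripts per cell. In a test of a like rise, each of 11 markers was set against the mean of the others, and 1 marker, ADIPOQ, exceeded it by 0.82 more in high than in low IMF (adjusted permutation p = 0.0391), which by the bound written beforehand counts against a like rise. That bound took every marker as made by fat cells alone, while GPD1, at 262 FPKM in high and 249 in low IMF, is also made by muscle fibres. Without GPD1, PLIN4, CFD and FABP4, a set chosen afterwards, none of 7 markers passed (lowest adjusted permutation p = 0.113). There the differences kept their directions except for PPARG, which went from 0.21 to -0.011. They were 0.63 for ADIPOQ and 0.94 for THRSP, but -1.25 for PLIN1 and -1.17 for GPAT3. The lost call does not undo the first result, but together these tests do not tell a like from an unequal rise. Sex of the animals is argued against, since the list kept a camera adjusted p of 3.52e-09 with the Y-linked level as a term. Chance is argued against for this list, since 1 of 100 splits, the real one, was as large (-log10 p 9.53, highest other 6.34). With 100 splits no smaller share was possible, so chance is not excluded. For the 5 genes higher chance is also argued against but not excluded, since 2 of 100 splits gave as many in the larger of their directions (highest other 5).

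More genes were higher than lower in high IMF at an unadjusted p. With the share of FPKM taken by the 10 most abundant genes as a term, 58.5% were higher, under the bound written beforehand. That top-10 share comes from the same FPKM and falls when other genes rise, so the fit cannot tell whether it accounts for the imbalance or follows from it. TMM scaling brought the percentage of higher genes to 54.5%, but it centres the fold changes and so fixes this balance. Scaling of the libraries thus cannot be told apart from a broad rise. Sequencing depth is argued against, since with the estimated reads as a term 90.2% were higher. Whether muscle genes of high abundance were lower or the rest higher stays open, as FPKM gives only relative levels, and the per-animal level of oxidative phosphorylation genes, whose call was lost under TMM scaling (0.508) while that of camera was kept (0.0156), shares this limit.

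Chance cannot be excluded for the count of lower genes, but the test set unlike counts side by side. The 1 lower gene was set against the larger direction of each other split, since a split and its mirror are the same split. By that count 5 of 100 splits, the real one included, gave 1 or more, the highest other giving 5. Those 5 were higher as drawn, in a split that shared 11 of 12 high animals with the real one, so they do not speak to lower genes. In the direction as drawn, 2 of 100 gave 1 or more lower, the highest other giving 1. Chance cannot be excluded for the number of lists passed by camera, since 29 of 100 splits gave 6 or more and the highest other gave 10. LEP and ATP6V1F, 349521 bases apart on chromosome 18, had r -0.50 in high and -0.26 in low IMF (permutation p = 0.0921 and 0.406, adjusted 0.147 and 0.541). Their rho was -0.45 and -0.10 (permutation p = 0.139 and 0.747), and r was -0.39 and -0.18 without the 2 farthest animals. The bound written beforehand for a shared segment, both r above 0.5, was not met. That does not exclude a shared segment, since a segment that differs in frequency between the groups need not show within them. Transcript use within a gene differed in 19 of 4847 genes by limma's diffSplice, among them PRKAG3, PLIN4 and GHR, named after their values were seen, but 8 of 100 splits gave as many (highest other 29), so chance cannot be excluded.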
